A study of Homo sapiens with 2 samples.

How the data were processed

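The series holds ATAC-seq of 2 human leukaemic cell lines, Jurkat and U937, with 1 library per line, and peak lists of the histone mark H3K27ac for the same lines. Per the labels' protocols, 25000 sorted live cells per line were transposed for 30 minutes at 37 °C with digitonin in the reaction, and the libraries were sequenced as paired ends of 76 cycles at an average of 30000000 reads per sample. The depth of each library is not given in the sources used here. Per the design text of the series, the H3K27ac lists are re-analyses of libraries from 2 other sources, 1 source per line, so a difference between the H3K27ac lists cannot be told apart from a difference between those sources.

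Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.1.0 and MACS2 were used and the build is hg19; which step each tool did, the MACS2 version and its settings are not given in the sources used here. The deposited files have no headers and were read by their standard layouts. The deposited ATAC lists give each summit's fold enrichment over the caller's local background, which is a ratio of pileups, and its −log10 p and −log10 q as the authors' caller wrote them, 1 list per library. The smallest deposited −log10 p was 2.00 in both ATAC lists, while the smallest −log10 q was 0.187 in Jurkat and 0.359 in U937. The deposited H3K27ac lists give a fold (ratio) and a −log10 p and −log10 q per region, with −log10 q from 2.02 in Jurkat and 2.00 in U937; the caller of these lists is not given in the sources used here. The authors' ATAC lists also give each summit's distance in bp from the start of its region. Coordinates are given 1-based on hg19, the build named for the ATAC samples, and reach 249240669 on chromosome 1; a build is not stated for the H3K27ac lists on their own. Fold enrichments are the authors' own values and were used only to describe, rank or filter regions within one list.

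Rows with the same start and end, which differ in their summit, were counted as 1 region represented by its summit of highest −log10 p. Chromosomes 1 to 22 and X were used, which left out 859 Jurkat and 286 U937 ATAC rows and 124 Jurkat and 4 U937 H3K27ac rows. Overlaps of at least 1 bp were found with bedtools 2.31.1; other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Regions with a −log10 q of at least 10 are called strict. A region is line-only where it overlaps no region of the other line's full list, and strict line-only where it is also strict in its own list. Shares have 95% Wilson intervals, which cover counting error only and treat regions as independent. Chance overlap was estimated by moving the second list by 1 random offset per chromosome, wrapped around, in 100 shifts; the shifts do not avoid stretches without alignable sequence, so chance is somewhat underestimated. For a share of 0, the limit given is 3 counts of the total.

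In both ATAC lists every row's fold and −log10 p were matched by a single whole summit pileup (the number of tags that overlap at the summit), with fold equal to pileup plus 1 over background plus 1 and p equal to the Poisson chance of a larger pileup. The misfit in −log10 p was below 0.001 in 100% of rows. Solved this way, the smallest background was 0.407 tags in Jurkat and 0.744 tags in U937. The U937 background was 1.83 times the Jurkat one as solved, which is the ratio of tags if tags were extended alike, and 2.30 times after division by the smallest region width of each list (180 bp in Jurkat, 143 bp in U937), which is that ratio if tags were extended to this width. The extension is not given in the sources used here. To match this background, and not a known depth, U937 summit pileups were thinned at random to 54.7% or 43.4% of tags in 20 draws and tested against their background scaled alike, at the smallest −log10 p of a strict Jurkat region (13); thinning cannot add or remove neighbouring regions.

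The blocks of the H3K27ac regions, which in this format can mark the strong parts of a region, held only 1-bp marks at both ends in all 50463 Jurkat regions and in 7561 of 7563 U937 regions. The planned comparison of gaps between blocks was therefore void. It was replaced, after the data were examined, by the share of positions at set distances from ATAC summits that lie in an H3K27ac region, with 95% intervals from resampling chromosomes. To match the U937 list in region width, Jurkat H3K27ac regions were also drawn at random in width bins of 20 bp, 20 times, which filled 7481 of 7563 places (median width 501 bp). Gene lists and consensus motifs had been fixed before the data were examined, but an hg19 sequence or annotation was not used here and the gene table at hand is on GRCh38, so genes, distances to promoters and motifs were not analysed. Regions are named by coordinates: the 3 line-only ATAC regions per line with the highest fold, by a rule set before the data were examined, and, by rules set afterwards, the 5 windows of 100000 bp per line with the most strict line-only regions and the stretches of at least 100000 bp without an ATAC region in 1 line that held the most regions of the other. In these stretches, regions with a −log10 q of at least 5 are called clear.

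With 1 library per line there is no replicate error and no test between lines, and the values describe these libraries. The functions for pileups, overlaps and coverage were tested on simulated data. Of summit pileups paired with backgrounds drawn at random from the real lists, 100% were recovered among 16546 Jurkat and 16045 U937 rows. The simulated values came from the formula that was solved, so this tested the solving and not the formula. With a known 29.99% of Jurkat and 29.8% of U937 regions kept in the second list, the overlap found was 29.99% and 29.8%. The kept regions were identical copies, so partial overlaps were not tested by this. Alternatives were a stricter threshold, every summit as a region, all sequences, lists of equal length, a reciprocal overlap of 50% and, added after the data were examined, a −log10 q of at least 2, a strict own list against the other list as deposited, thinning and removal of regions with a summit pileup of at most 3 tags.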

Results

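Accessible chromatin was mapped by ATAC-seq, in which a transposase cuts and tags open DNA, in Jurkat, a human T lymphocyte line, and in U937, a human myeloid line often used as a model of monocytes. Regions carrying H3K27ac, an acetylated histone found at active promoters and enhancers, were listed for the same lines from published libraries of other sources. The series is titled for the position of transcription factor classes within enhancers. Its lists allow 3 comparisons: accessible regions between the lines, H3K27ac regions between the lines, and the position of accessible sites relative to H3K27ac within each line. Each line had 1 ATAC library and 1 H3K27ac list, so no difference between the lines has a replicate check.

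The accessible regions of Jurkat outnumbered those of U937 in the lists as deposited, and the order reversed once weak regions were left out. Jurkat had 197568 regions covering 56.5 Mb and U937 had 145845 covering 58.5 Mb. At a −log10 q of at least 10, called strict from here on, 12183 Jurkat regions (6.17%) and 42550 U937 regions (29.2%) remained, 3.49 times as many in U937. Strict regions were of similar width in both lines, with a median of 733 bp in Jurkat and 662 bp in U937, against 181 bp and 287 bp over all regions. U937 regions more often held 2 or more summits, in 16.0% of regions against 3.36% in Jurkat, and adjacent summits of one region lay a median of 306 bp apart in U937 and 324 bp in Jurkat.

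Most regions of the deposited Jurkat list had few tags at the summit. The summit pileup was at most 3 tags in 125001 Jurkat regions (63.3%) and in 11990 U937 regions (8.22%). In Jurkat 98570 regions (49.9%) had the smallest width of the list, 180 bp, while in U937 25657 regions (17.6%) had the smallest width, 143 bp. The median pileup was 3 tags over all Jurkat regions and 9 tags over all U937 regions, and among strict regions it was 25 and 34 tags. The smallest background solved from the lists was higher in U937, by 1.83 times as solved and by 2.30 times per bp of the smallest region width. After U937 pileups were thinned by these ratios, 25167 and 19461 U937 regions passed the strict Jurkat threshold, against 12183 in Jurkat.

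**Figure D1:**
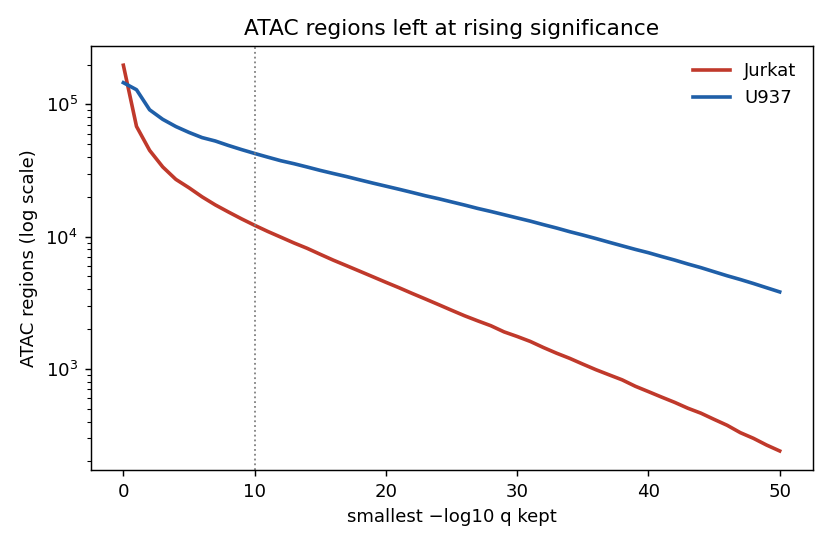
Number of ATAC regions (log scale) kept in each line at rising minimum −log10 q, 1 line per library. Jurkat starts above U937, at 197568 against 145845 regions, and lies below it at the dotted line at 10, with 12183 against 42550.

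Most strict Jurkat sites were also accessible in U937, and the share of strict U937 sites accessible in Jurkat depended on whether weak Jurkat regions were counted. Of strict Jurkat regions 77.1% (95% interval 76.3 to 77.8%) overlapped a U937 region of any strength, against 5.57% after random shifts of the U937 list. Of strict U937 regions 50.4% (49.9 to 50.9%) overlapped any Jurkat region, against 6.56% after shifts. With both lists strict the shares were 69.3% (68.5 to 70.1%) in Jurkat and 19.9% (19.6 to 20.3%) in U937. The low U937 share was largely set by list sizes: 8444 of 12183 strict Jurkat regions overlapped 8486 of 42550 strict U937 ones. Overlap with the full lists left 2793 strict Jurkat-only and 21110 strict U937-only regions. Over the full lists the shares were lower, at 22.4% of Jurkat regions (22.2 to 22.5%) and 29.6% of U937 regions (29.4 to 29.8%), against 3.34% and 4.50% after shifts. Sharing rose with signal in both lines: with each list split by fold into 4 groups of equal size, 6.15% of Jurkat and 13% of U937 regions were shared in the group of lowest fold, and 54.7% and 49.7% in the group of highest fold. Regions of at most 3 tags in Jurkat overlapped U937 in 7.86% of cases, 2.67 times the share after shifts.

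Strict sites found in 1 line were narrower than shared ones. Median widths were 573 bp for strict Jurkat-only against 784 bp for strict shared Jurkat regions, and 564 bp for strict U937-only against 808 bp for strict shared U937 regions. Their median folds within each list were close, at 9.20 and 9.22 in Jurkat and at 9.42 and 9.33 in U937. Windows of 100000 bp with at least 3 such sites held 46.7% of the 21110 strict U937-only and 3.22% of the 2793 strict Jurkat-only sites. With the U937 set drawn down to 2793 sites the share was 2.53% (1.65 to 3.69% over 100 draws), a range that includes the Jurkat value.

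The 3 line-only regions of highest fold in each line differed in listed H3K27ac, from lists of 50463 Jurkat and 7563 U937 regions. Over all strict line-only summits, 72.4% of Jurkat-only ones lay in Jurkat H3K27ac and 3.31% of U937-only ones in U937 H3K27ac. The Jurkat-only region of highest fold lay on chromosome 10 at 129091839 to 129092306, with a fold of 20.7 and 54 tags at its summit. The next lay on chromosome 11 at 123551672 to 123552271, with a fold of 18.2 and 56 tags, and on chromosome 5 at 33642051 to 33642960, with a fold of 18.1 and 2 summits. All 3 overlapped a Jurkat H3K27ac region, with H3K27ac folds of 2.94, 3.96 and 4.11, and none overlapped a U937 one. The U937-only regions of highest fold lay on chromosome 20 at 50885761 to 50886237, with a fold of 26.1 and 62 tags, on chromosome 7 at 50894446 to 50894929, with a fold of 23.8, and on chromosome 6 at 12208413 to 12209032, with a fold of 23.3. Of these, the region on chromosome 6 overlapped a U937 H3K27ac region, at 12208757 to 12209559 with an H3K27ac fold of 4.2, though its summit at 12208630 lay outside it, and none overlapped a Jurkat one.

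Dense groups of line-only sites stood out at several loci. In Jurkat, chromosome 14 from 98600001 to 98700000 held 11 accessible regions, 5 of them strict and Jurkat-only, and 20.7 kb of Jurkat H3K27ac; U937 had no ATAC and no H3K27ac region there. Chromosome 8 from 10900001 to 11000000 held 5 strict Jurkat-only regions with 7.93 kb of Jurkat H3K27ac, and chromosome 2 from 240200001 to 240300000 held 4 with 22.6 kb, again with no region of either kind in U937. Chromosome 3 from 117800001 to 117900000 held 4 strict Jurkat-only regions with 10.03 kb of Jurkat H3K27ac, and 1 U937 ATAC region. Chromosome 18 from 67600001 to 67700000 held 3 with 11.7 kb, and 9 U937 regions lay in the same window. In U937, chromosome 15 from 80200001 to 80300000 and chromosome 17 from 72500001 to 72600000 each held 10 strict U937-only regions, and 9 each lay on chromosome 2 from 12000001 to 12100000, chromosome 6 from 36600001 to 36700000 and chromosome 10 from 75600001 to 75700000. All 5 U937 windows also held other Jurkat ATAC regions, from 4 to 13, and Jurkat H3K27ac, from 1.57 to 8.16 kb. U937 H3K27ac in them ranged from 0.708 to 2.78 kb.

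Some stretches with many clear U937 sites, at a −log10 q of at least 5, held no Jurkat ATAC region of any strength. The stretch with the most was on chromosome 9, from 21374398 to 22354220 (980 kb), where U937 had 86 accessible regions, 49 of them clear, and Jurkat had none. Next to it, from 21119576 to 21373973, U937 had 23 regions, 12 of them clear, and Jurkat again none. No Jurkat H3K27ac region lay between 21119808 and 23590709 on that chromosome, where Jurkat had 23 and U937 128 ATAC regions. Before position 23291080 the only Jurkat ATAC regions in this part started at 21373974, 22354221 and 22701195, with summit pileups of 5, 4 and 4 tags. A second stretch, on chromosome 14 from 22472014 to 23024821 (553 kb), held 26 U937 regions, 13 of them clear. It held 6 Jurkat H3K27ac regions, 1 crossing its left end and 5 in its last 50.2 kb. At a −log10 q of at least 5 the lists held 61343 U937 and 23415 Jurkat regions, which favours stretches of clear U937 regions. In total 4 stretches of at least 100000 bp held 10 or more clear U937 regions and no Jurkat region. No stretch without a U937 region held more than 9 clear Jurkat regions. Counted over regions of any strength the order was the opposite: 204 stretches held 30 or more Jurkat regions and no U937 region, against 1 of the reverse kind. The richest of them, on chromosome 4 from 178517479 to 179443792 (926 kb), held 86 Jurkat regions, 0 of them clear, and no Jurkat H3K27ac.

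**Figure D2:**
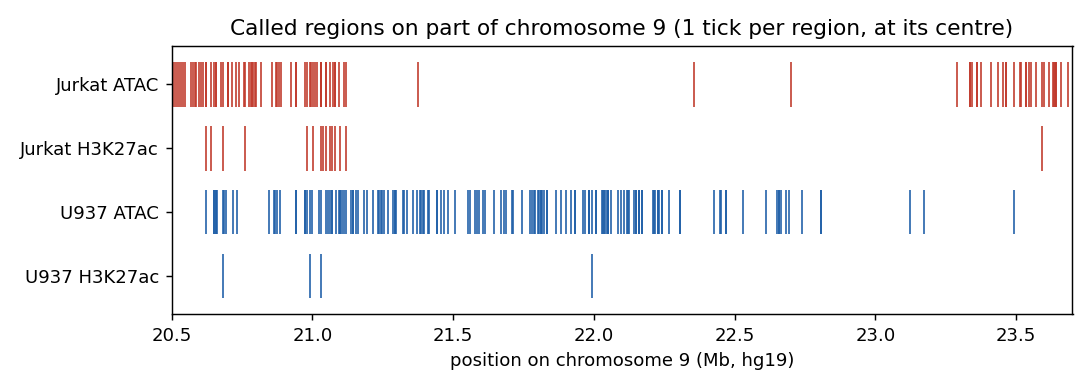
Called ATAC and H3K27ac regions of both lines on part of chromosome 9 (position in Mb, hg19), 1 tick per region and 1 row per list. Between positions 21374398 and 22354220 the U937 ATAC row holds 86 regions and both Jurkat rows are empty.

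The H3K27ac lists differed greatly in size. Jurkat had 50463 regions covering 58.9 Mb with a median width of 1055 bp, and U937 had 7563 regions covering 4.56 Mb with a median width of 495 bp, so the Jurkat list was 6.67 times as long. By an overlap of at least 1 bp, most U937 regions had a Jurkat counterpart and most Jurkat regions had no U937 one: 75.0% of U937 regions (74.0 to 75.9%) overlapped a Jurkat region, against 3.40% after shifts, and 11.2% of Jurkat regions (10.9 to 11.4%) overlapped a U937 region, against 0.511%. The low Jurkat share was largely set by list length: 5670 of the 7563 U937 regions overlapped 5631 of the 50463 Jurkat ones. With a reciprocal overlap of 50% the shares were 15.7% of U937 and 2.35% of Jurkat regions. With the Jurkat list shortened to its 7563 strongest regions, 44.6% of Jurkat and 44.8% of U937 regions overlapped. Chromosome 19 held 7.30% of U937 and 3.69% of Jurkat H3K27ac regions, while it held 4.02% and 4.51% of strict ATAC regions.

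Regions with H3K27ac in 1 line overlapped ATAC regions of that line more often than of the other. The 1893 U937-only H3K27ac regions overlapped a U937 ATAC region in 89.6% of cases (88.2 to 90.9%) and a Jurkat ATAC region in 8.72% (7.53 to 10.1%). The latter share was partly fixed by definition. These regions overlap no Jurkat H3K27ac region, and Jurkat H3K27ac held 83.7% of strict Jurkat ATAC summits. Over all U937 H3K27ac regions, 63.6% overlapped a Jurkat ATAC region, against 5.67% after shifts. The 44832 Jurkat-only H3K27ac regions overlapped a Jurkat ATAC region in 66.4% (66.0 to 66.8%) and a U937 ATAC region in 46.6% (46.1 to 47.0%). Of Jurkat H3K27ac regions shared with U937, 93.1% overlapped a Jurkat and 99.5% a U937 ATAC region, and of shared U937 H3K27ac regions, 82.0% overlapped a Jurkat and 96.6% a U937 ATAC region. Over all regions, 69.4% of Jurkat H3K27ac regions (69.0 to 69.8%) and 94.8% of U937 ones (94.3 to 95.3%) overlapped an ATAC region of their line, against 9.11% and 5.15% after shifts. A strict ATAC region of their line was overlapped by 21.5% of Jurkat (21.2 to 21.9%) and 87.2% of U937 H3K27ac regions (86.5 to 88.0%). Jurkat H3K27ac regions without an ATAC region were narrower, with a median width of 604 bp against 1276 bp, and had a median fold of 2.95 against 3.42.

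Strict accessible sites lay in the listed H3K27ac of their own line more often in Jurkat than in U937, and the Jurkat share depended on the length of its H3K27ac list. List sizes limit this comparison. Jurkat had 50463 H3K27ac regions for 12183 strict summits, and U937 had 7563 for 42550. Of strict Jurkat summits 83.7% (83.0 to 84.3%) lay in a Jurkat H3K27ac region, against 2.12% after shifts, and 39.2% (38.3 to 40.1%) lay in its 7563 strongest H3K27ac regions. These had a median width of 1595 bp, against 495 bp in the U937 list. Of strict U937 summits 6.20% (5.97 to 6.43%) lay in a U937 H3K27ac region, against 0.181% after shifts, and 38.7% (38.2 to 39.1%) lay in a Jurkat H3K27ac region, against 2.13%. Over all summits the shares in the own list were 18.5% (18.4 to 18.7%) in Jurkat and 2.21% (2.14 to 2.29%) in U937. With each list split by fold into 4 groups, the share rose in Jurkat from 2.32% in the lowest to 52.6% in the highest, and in U937 from 0.579% to 5.51%.

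Sites accessible in Jurkat alone lay in listed H3K27ac of Jurkat more often than of U937. For sites accessible in U937 alone, the comparison turned when the Jurkat H3K27ac list was shortened to its strongest regions. Of strict Jurkat-only summits 72.4% (70.7 to 74.1%) lay in Jurkat H3K27ac, against 1.99% after shifts. In U937 H3K27ac the count was 0 of 2793, which allows a share of up to 0.107%, against 0.161% after shifts. This low share was largely fixed by definition. Jurkat-only sites overlap no U937 ATAC region, and 94.8% of U937 H3K27ac regions overlap one. With the Jurkat list shortened to 7563 regions, the 72.4% became 9.42% (8.39 to 10.6%). Of strict U937-only summits 3.31% (3.08 to 3.56%) lay in U937 H3K27ac and 9.18% (8.80 to 9.58%) in Jurkat H3K27ac. With the shortened Jurkat list, 0.407% (0.330 to 0.503%) of strict U937-only summits lay in Jurkat H3K27ac, below the 3.31% in U937 H3K27ac. U937-only sites overlap no Jurkat ATAC region, and Jurkat H3K27ac regions without one had a lower median fold, 2.95 against 3.42. Keeping the strongest regions also raised their median width from 1055 to 1595 bp. The turn therefore cannot be told apart from this selection.

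Where an H3K27ac region held the strongest summit of an ATAC region, that summit lay near the centre more often than an even spread gives. This held in both lines, taking the strongest where an H3K27ac region held several. The summit lay in the central 20% of the H3K27ac region's length in 38.7% of 31526 Jurkat regions (38.2 to 39.3%) and in 40.6% of 3055 U937 regions (38.8 to 42.3%). It lay a median of 470 bp from the nearer end in Jurkat and 309 bp in U937. Each ATAC region was counted by its strongest summit alone, and its other summits were left out. Counted this way, no summit lay in 37.5% of Jurkat and 59.6% of U937 H3K27ac regions, a single one in 53.3% and 38.3%, and 2 or more in 9.17% and 2.13%. In U937 most H3K27ac regions therefore overlapped an ATAC region without holding its strongest summit.

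U937 H3K27ac regions covered the flanks of accessible sites more often than the summit itself. In Jurkat this held for short H3K27ac regions taken alone. With the full Jurkat list it held by little around strict summits and not over all summits. Around strict U937 summits, coverage by H3K27ac regions was 6.20% at the summit, 8.53% at 250 bp and 5.48% at 500 bp, a ratio of 250 bp to the summit of 1.38 (95% interval 1.34 to 1.41). Over all U937 summits the ratio was 1.35 (1.32 to 1.38). Around strict Jurkat summits coverage was 83.7% at the summit, 84.6% at 200 bp, 84.2% at 250 bp and 70.5% at 500 bp. The ratio at 250 bp was 1.007 (1.002 to 1.010) over strict and 0.970 (0.967 to 0.973) over all Jurkat summits. With Jurkat H3K27ac regions up to the U937 median width of 495 bp, the ratio was 2.1 (1.72 to 2.64) over strict and 1.08 (1.04 to 1.12) over all Jurkat summits. These short regions covered 0.583% of strict and 0.838% of all Jurkat summits. With Jurkat regions drawn to the U937 widths and number, the mean ratio was 1.07 over strict and 0.967 over all summits. The intervals come from resampling chromosomes of 1 library and do not include variation between libraries.

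**Figure D3:**
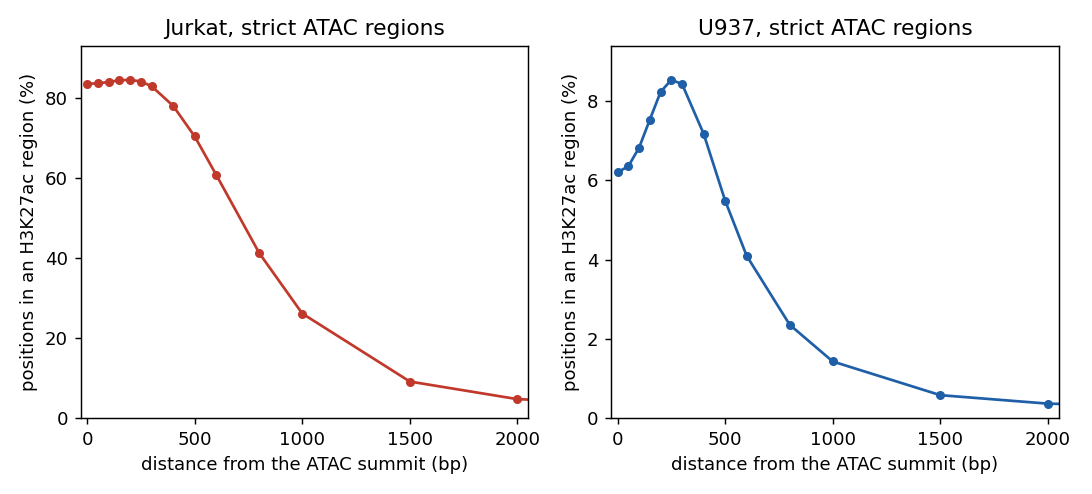
Share of positions (%) that lie in an H3K27ac region of the same line at each distance (bp) from strict ATAC summits, averaged over both sides, for Jurkat (left) and U937 (right, on its own scale). Coverage in U937 rises from 6.20% at the summit to 8.53% at 250 bp, and in Jurkat it is 83.7% at the summit and 84.6% at 200 bp.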

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

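The settings with H3K27ac lists of equal length were chosen after the data were examined. Jurkat-only and U937-only accessible sites went opposite ways in their H3K27ac: the share in own minus the share in the other line's H3K27ac regions was 9.89 percentage points for Jurkat-only and -5.61 percentage points for U937-only summits over the full ATAC lists. With 1 library per line this difference was not tested. With H3K27ac lists of equal length, which kept the strongest Jurkat regions, the values were 0.617 and 0.272 percentage points, both higher for the own line. Line-only sites overlap no ATAC region of the other line, and most H3K27ac regions overlap an ATAC region of their line. A low share in the other line's H3K27ac was therefore partly fixed by definition.

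The mitochondrial sequence, which enters no comparison, held 22 rows of the Jurkat ATAC list, 20 of the U937 ATAC list and 5 of the Jurkat H3K27ac list. It held 2 rows of the U937 H3K27ac list.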

How the results depend on the processing

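The settings at a −log10 q of 2, the strict own list against the full other list, thinning, removal of weak pileups, and the coverage ratio and the line-only difference with their settings were chosen after the data were examined. The count of ATAC regions held within 1.5 times with every summit as a region and with all sequences. At a −log10 q of at least 10 it was 12183 in Jurkat and 42550 in U937, and at 2 it was 44888 and 90952. The log2 ratio of counts, Jurkat over U937, was 0.44 as deposited and reversed to -1.80 at 10, to -1.02 at 2, and to -1.05 and -0.68 at the strict threshold with U937 thinned (equal extension, then extension equal to the smallest width). The share of Jurkat regions shared with U937 was 69.3% with both lists strict, 28.2% with equal list lengths, 13.3% with a reciprocal overlap of 50%, 77.1% with only the own list strict, 53.7% at 2 and 46.6% without summit pileups of at most 3 tags. For U937 these shares were 19.9%, 27.6%, 18.1%, 50.4%, 26.3% and 24.7%. H3K27ac regions with a −log10 q of at least 5 numbered 33073 in Jurkat and 1587 in U937, and 3.89% and 81.0% of them were shared; equal lengths gave 44.6% and 44.8%, and the reciprocal overlap 2.35% and 15.7%. ATAC summits in own H3K27ac were 83.7% (Jurkat) and 6.20% (U937) for strict regions. With the Jurkat H3K27ac list shortened, the share over all Jurkat summits was 4.34%, against 18.5% with the full list, and over strict ones 39.2%. Coverage 250 bp from the summit over coverage at the summit, 0.970 in Jurkat, was 0.991 at 200 bp, 0.937 at 300 bp and 0.983 with the list shortened, and turned to 1.01 for strict regions and 1.08 with regions up to the U937 median width. With regions drawn to the U937 widths and number it was 0.967 over all and turned to 1.07 over strict summits. In U937, where it was 1.35, it stayed within its interval for strict regions and at 300 bp, and was 1.30 at 200 bp and 2.89 with regions up to that width. Line-only summits in own minus other H3K27ac gave, in Jurkat, 0.617 percentage points with equal lengths, 72.4 for strict regions and 9.42 with both. In U937 the -5.61 points became -5.87 for strict regions and reversed to 0.272 with equal lengths and 2.90 with both. Where no value is named the cause was not tested. Gaps between blocks, blocks as regions, distal regions, gene lists and motifs were not run, and the lack of replicates left no library to leave out. No paired analysis was possible because each line has 1 library. What depth limits was not tested beyond thinning, since the depth of each library is not known here.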

Other observations

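All patterns below were found by looking through the data. The tests of closed chromatin and of alignable sequence, the inner part of chromosome 14, and the coverage ratios of wide regions, of strict summits at short regions and of Jurkat regions drawn to the U937 widths were chosen after the result was seen. Among stretches without a U937 ATAC region, those with the most clear Jurkat regions lay on chromosome 2, at 240144279 to 240386951 (243 kb, 24 Jurkat ATAC and 27 Jurkat H3K27ac regions) and at 165871837 to 166060590 (189 kb, 23 and 14 regions), with 9 clear ATAC regions each. The 8 Jurkat stretches with the most clear regions held from 10 to 27 Jurkat H3K27ac regions and no U937 one, in a U937 list of 7563 regions.

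In the stretches of chromosomes 9 and 14 without Jurkat ATAC regions, sequence to which reads cannot be aligned is argued against by 86 and 26 U937 regions on the same build (49 and 13 clear), although parts may be unalignable. Closed chromatin at normal copy number is not decided, since the stretches were picked for lacking Jurkat regions. Windows of the length of the chromosome 9 stretch and with a U937 region numbered 2909. None of these lacked Jurkat regions of at most 3 tags (1st percentile among windows with a Jurkat region 10.15, lowest 13 in the 483 with as many U937 regions). Windows wholly between 21119808 and 23291080 on chromosome 9 cannot be among the 2909, since the only Jurkat regions there had 5, 4 and 4 tags. The 2909 therefore do not cover the locus itself. At the length of the chromosome 14 stretch, 4 of 5097 windows lacked Jurkat regions of at most 3 tags (1st percentile 5, lowest 0). Loss of the DNA in Jurkat may account for the stretch of chromosome 9 and met its test, since no Jurkat H3K27ac region lay there while 99.8% of windows with at least as many U937 regions held one, but closed chromatin would also leave none, and copy number was not analysed here. Loss of the whole stretch of chromosome 14 is argued against by its 6 Jurkat H3K27ac regions (98.3% of windows with as many U937 regions held at least 1). Its part from 22472867 to 22974581 (502 kb, 22 U937 regions) was picked for holding no Jurkat region of either kind, so loss of that part stays open and untested.

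The reversal of the count of accessible regions was weighed against chance and depth. Chance as the source of all Jurkat regions of at most 3 tags is argued against, since their summits lay in Jurkat H3K27ac 1.66 times as often as after shifts (3.24% against 1.95%, highest shift 2.04%). The excess is small and the shifts understate chance, so many of them may still be chance pile-ups. Depth as the cause of the U937 excess among strict regions cannot be told apart from other causes: thinning by the ratio of backgrounds left 1.60 or 2.07 times as many in U937, down from 3.49 times, but these ratios rest on an assumed tag extension and the depth of each library is not known. Cell quality and a difference between the lines also stay open, with 1 library per line.

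The lower H3K27ac coverage at U937 summits than 250 bp away was weighed against the length of the list and of its regions. List length stays open: the Jurkat list shortened alike gave a ratio of 0.983 (0.979 to 0.987), below the bound set before it was seen, but keeping the strongest regions raised their median width from 1055 to 1595 bp, against 495 bp in U937, and the ratio was lower for wide regions. Short regions as the cause cannot be told apart from a difference between the lines or the H3K27ac sources: Jurkat regions up to the U937 median width gave 1.08 (1.04 to 1.12) over all summits, an interval that crosses the bound of 1.1 set before this value was seen, and 2.1 (1.72 to 2.64) over strict summits. At these widths U937 gave 2.89 (2.68 to 3.13) and, over strict summits, 3.55 (3.22 to 3.95), and wider regions gave 0.965 (0.963 to 0.967) in Jurkat and 1.1 (1.09 to 1.12) in U937, so the ratio rose with short regions in both lines but differed between the lists, also at like widths. Jurkat regions drawn 20 times to the widths and number of the U937 list gave 0.967 (bounds 0.930 to 0.997) over all and 1.07 (1.00 to 1.12) over strict summits, below the 1.35 and 1.38 of U937, but the last upper bound passes the 1.1 set before, so widths and length together also stay open.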
